A study of Mus musculus with 10 samples.

How the data were processed

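RNA from 5 sorted mouse cell types was measured on Affymetrix arrays, with 2 arrays per cell type. Per the labels' protocols, cells were sorted from fresh tissue on a FACSAria II without culture, total RNA was extracted with RNeasy kits and labelled with the GeneChip 3′ IVT Express kit. Per the submitters' processing notes the arrays were summarised with GCRMA, whose version is not given in the sources used here, and the deposited values are on a log2 scale. The series gives these values in 2 tables, whose largest difference over the 10 arrays was 0. In 1 of them 28 further columns belong to samples of another series and were not used here.

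All computation started from the deposited log2 values. Of 45101 probe sets, 64 are controls, 34945 list a single gene, 932 several genes and 9160 none. Single-gene probe sets were kept and 34741 symbols were matched to the gene table by gene number, with 0 changed. Each of the 18193 genes was represented by its brightest probe set over all arrays (9010 genes had several), and a gene was tested when at least 2 arrays reached a log2 value of 4, which left 11730 genes. Of these, 1417 rest on a probe set ending in _x_at or _s_at, which other transcripts may share. The lowest value on the arrays was 2.22, so changes against genes near it are compressed. 

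A linear model with 5 group means was fitted over the 10 arrays with limma 3.58.1 in R 4.3.3 (5 residual and 1.92 prior degrees of freedom), with statmod 1.5.0 for the random block, and p-values were moderated by empirical Bayes and adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Of the 11730 genes, those with an unadjusted p under 0.05 numbered 6252 for MEP against HSC, 2597 for EDif against EPro, 4714 for CLDC against EPro, 4463 for CLDC against EDif, 8556 for skin against blood and 5924 for the difference of the epidermal and the blood step. Those called with a change of at least 2-fold numbered 5058, 922, 2948, 2605, 6504 and 4845. Skin against blood weighs each cell type of a lineage alike.

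The comparisons, their main settings and the gene lists were fixed before the data were examined. The 28 lists (446 genes, 384 tested) cover sort genes, blood stem cells, erythroid, heme synthesis, megakaryocyte, myeloid, lymphoid and pan-hematopoietic genes, cell cycle, DNA methylation machinery, polycomb, basal epidermis, spinous layer, cornified envelope and granular layer, epidermal lipid barrier, companion layer and outer root sheath keratins, inner root sheath, hair shaft, follicle stem and outer root sheath, epithelial adhesion, immediate early and heat shock, melanocyte, skin immune, fibroblast, endothelial, sebocyte, muscle and sex-linked genes. Lists of at least 5 tested genes were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Counts adjusted over the list alone repeat the adjustment over its members. The genes named are the 10 largest rises and 10 largest falls among genes past the threshold whose arrays do not overlap between the groups, with unnamed gene models left out, then 2 to 4 members of each list, first those past the threshold with the largest change and then well-known members that did not pass, and the genes of the sorting markers. Ly6a, which encodes the sorting marker Sca1, is not named by a single-gene probe set.

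The fit was tested on simulated data with 11730 genes, 200 of them changed. With the same spread in all cell types, 0% were recovered at a change of log2 1 in each of the 4 comparisons of cell types. At log2 2 the shares were 45.0% for MEP against HSC, 39.5% for EDif against EPro, 41.0% for CLDC against EPro and 36.0% for CLDC against EDif. At log2 4 they were 84.0%, 84.5%, 79.5% and 82.5%, with 7.18%, 3.98%, 4.22% and 5.71% of the called genes false. With each cell type's own spread the recovered shares at log2 4 were 83.5%, 81.5%, 84.0% and 88.0%, and the false shares 0%, 28.5%, 23.6% and 61.1%.

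Alternatives were quantile normalization, median centring, other filters and probe set choices, an intensity trend with a robust prior, the arrays of the compared lineage alone, a replicate block, a change of at least log2 1 and each array left out in turn. Skin against blood was also fitted as 2 groups, with and without cell type as a random block. Ranges over alternatives omit the estimated correlation. Weights by the spread of each cell type, a fit without the CLDC arrays, a block for sex-linked expression and a crossed replicate block were added after the data were seen.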

Results

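Gene expression was measured in 5 mouse cell types sorted directly from tissue, each on 2 arrays (10 arrays in all). The arrays are the expression part of a study of DNA methylation during blood and skin differentiation. The blood cells came from C57BL/6 bone marrow. They were hematopoietic stem cells (HSC), which renew themselves and give rise to all blood lineages, and megakaryocyte-erythroid progenitors (MEP), which produce platelets and red cells. The skin cells came from CD-1 mice. They were epidermal progenitors (EPro), differentiated epidermal cells (EDif) and cells labelled as differentiated cells of the companion layer (CLDC), a thin sheet inside the hair follicle between the outer and the inner root sheath. Over all probe sets the median log2 value per array lay between 2.65 and 3.02, and between 39.8% and 44.3% of the probe sets reached a log2 value of 4, the expression minimum used here. The labels call the arrays of a cell type biological replicates without saying that they came from separate animals, which only the sex-linked genes of EPro and EDif show, so elsewhere the spread between arrays may be technical. Changes are given in log2 units with the standard error (SE) of the fit, and levels as mean ± SD of 2 arrays. Where the mean of a group lay under the minimum, a fold is given only as a lower bound, computed with values under 4 raised to 4, and a difference between steps is given no size. List medians floored at 4 use the same values.

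Principal component 1 (53.2% of the variance) separated skin from blood and component 2 (18.2%) HSC from MEP. Replicate arrays lay closest for MEP, with 284 of the 11730 tested genes at least 2-fold apart. That number was 685 for HSC, 796 for EPro, 3224 for EDif and 3470 for CLDC. Several immune and pigment cell genes separated the EDif arrays. Cd207, a marker of Langerhans cells, was at 14.75 on replicate 1 and 8.66 on replicate 2. The EPro and EDif replicates also differed at the 4 sex-linked genes. Xist, from the inactive X of females, was at 2.48 and 14.42 in EPro and 2.30 and 14.20 in EDif. The Y-linked Eif2s3y was at 11.14 and 11.18 on replicates 1 and the lowest value on replicates 2. Both CLDC arrays carried Xist (13.49 and 12.84) and Eif2s3y (9.35 and 8.88). No sex-linked gene passed in any comparison.

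**Figure D1:**
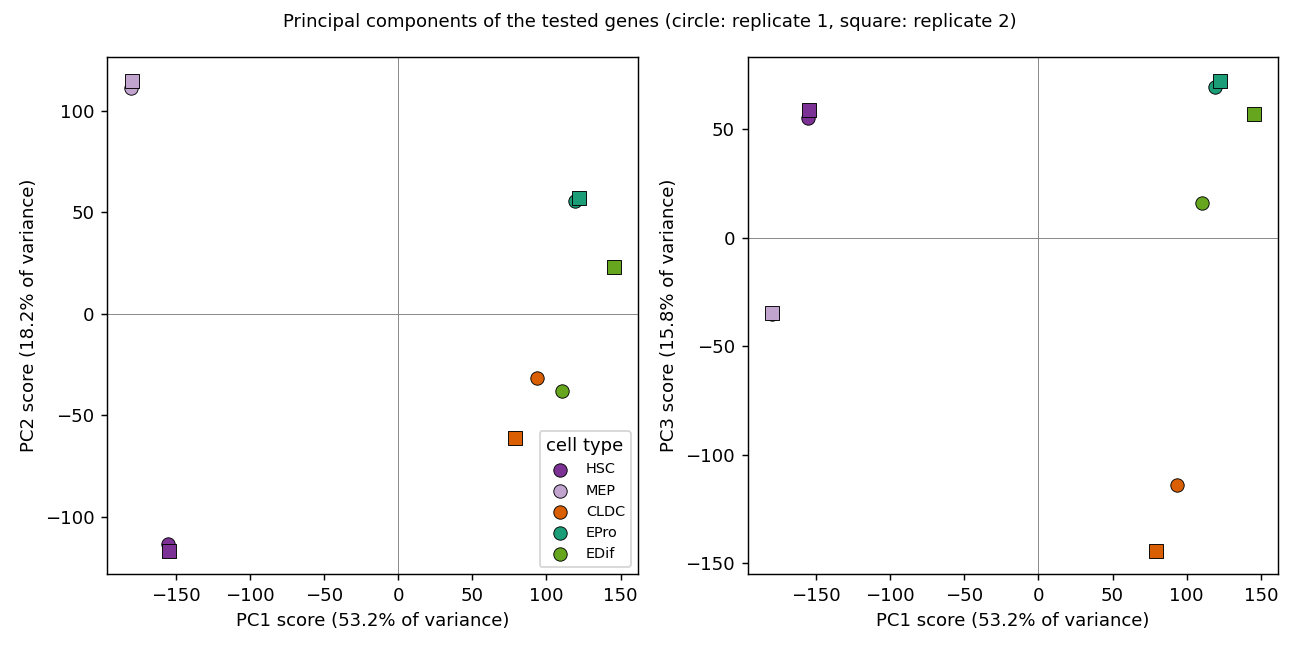
Scores of the 10 arrays on the first 3 principal components of the tested genes, with the share of variance on each axis (left, components 1 and 2; right, components 1 and 3). Colours are cell types, circles replicate 1 and squares replicate 2: skin and blood lie on opposite sides of component 1, and the EDif arrays lie farther apart than the EPro arrays.

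The genes of the sorting markers were examined first. Kit, the stem cell factor receptor used to sort both blood types, was at 12.68 ± 0.03 in HSC and 12.10 ± 0.22 in MEP. Cd34 and Flt3, whose surface proteins were sorted against in HSC, had transcript levels of 10.90 ± 0.12 and 9.79 ± 0.29 there, and both fell in MEP (Cd34 by at least 119.8-fold, adjusted p = 0.00305; Flt3 by at least 55.2-fold, adjusted p = 2.34e-04). Krt14, the basal keratin whose promoter drove the green reporter, was at 15.39 ± 0.09 in EPro and 14.20 ± 0.07 in EDif, and fell between them (-1.19 ± 0.21, adjusted p = 0.0205). Krt10, the suprabasal keratin of the red reporter, was at 16.01 ± 0.27 in EPro and 16.77 ± 0.23 in EDif. It was the highest value of either EDif array, so its test (adjusted p = 0.515) says little. Itga6, the integrin used to tell basal from suprabasal cells, fell in EDif (-2.09 ± 0.26, adjusted p = 0.00601). On the arrays labelled CLDC, Lhx2, whose reporter was sorted against, had a level of 13.01 ± 0.12, above EDif (2.57 ± 0.58, adjusted p = 0.0201) and EPro (5.92 ± 0.58, adjusted p = 6.41e-04). Krt6a, the keratin of the reporter sorted for, was at 10.84 and 8.29 on those arrays and did not differ from EPro by the test (0.06 ± 0.81, adjusted p = 0.980), while Krt75, a keratin known from the companion layer, was at 12.47 ± 0.58 and at least 355-fold above EPro (adjusted p = 4.07e-05). Cd34 was at 7.66 and 12.30 on the CLDC arrays, which were sorted as lacking its protein.

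**Figure D2:**
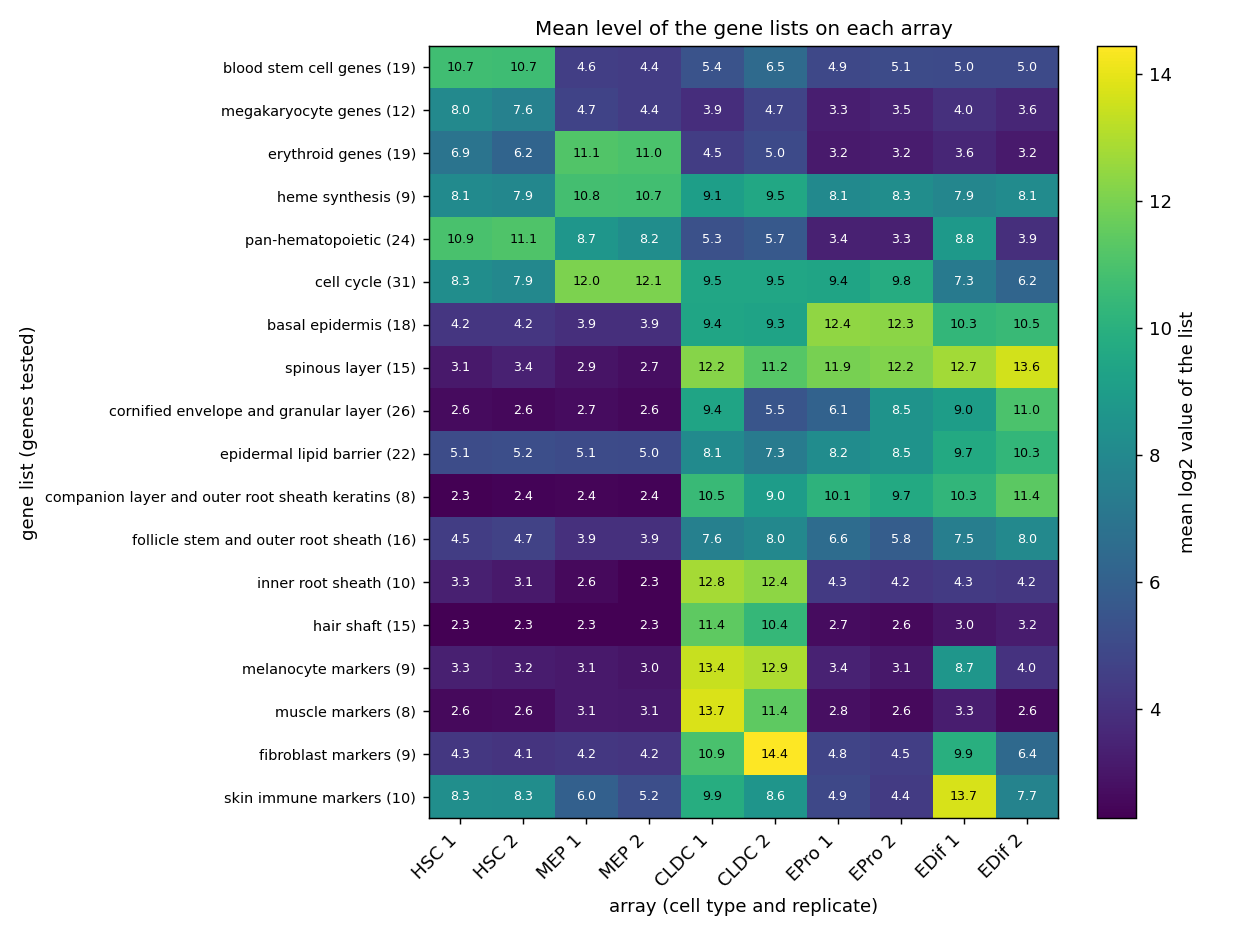
Mean log2 value of 18 gene lists (rows, with the number of tested genes) on each of the 10 arrays (columns), colour and number giving the mean. The hair shaft, inner root sheath, melanocyte and muscle lists are highest on the CLDC arrays, and the skin immune list is higher on EDif replicate 1 than on replicate 2.

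The comparison of MEP with HSC addresses the commitment of blood stem cells to the red cell and platelet lineage. In MEP, genes of red cells, of heme synthesis and of cell division rose, and genes known from stem cells fell. Rhd, which encodes a red cell blood group antigen, rose by at least 545-fold, adjusted p = 1.99e-06, and Gata1, the transcription factor that drives red cell formation, rose (6.59 ± 0.28, adjusted p = 9.36e-06). Mecom and Hlf, transcription factors needed for stem cell self-renewal, fell by at least 521-fold, adjusted p = 3.78e-05, and by at least 586-fold, adjusted p = 7.47e-05. Of 11730 genes, 5532 passed the adjusted p threshold of 0.05, 2648 higher and 2884 lower in MEP. Median centring moved the median of all genes from 0 to 0.22 log2 units and turned the split to 2971 higher and 2526 lower, and quantile normalization turned it to 2840 and 2721.

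All 31 tested cell cycle genes rose in MEP (median 3.44, camera adjusted p = 1.25e-12, and adjusted p = 0.344 with an estimated correlation). Plk1, Aurka and Aurkb, kinases of mitosis, rose (Plk1 by at least 131-fold, adjusted p = 1.24e-04, Aurka by at least 145-fold, adjusted p = 3.96e-05, and Aurkb, 7.31 ± 0.68, adjusted p = 1.91e-04). Of 19 blood stem cell genes, 18 fell and 1 did not pass, and 18 fell adjusted over the list alone (median -6.30, or -5.17 floored at 4, camera adjusted p = 4.67e-08, and adjusted p = 0.0632 with an estimated correlation). Procr and Fgd5, surface and signalling genes used to mark HSC, fell by at least 420.4-fold, adjusted p = 7.11e-05, and by at least 164-fold, adjusted p = 1.14e-04. Thy1, a surface protein of HSC, did not pass (adjusted p = 0.442). Of 19 erythroid genes, 15 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone (median 5.61, or 5.34 floored at 4, camera adjusted p = 2.96e-06, and adjusted p = 0.123 with an estimated correlation). Cldn13 and Rhag, which encodes the Rh-associated glycoprotein, had the largest rises among them (Cldn13 by at least 313-fold, adjusted p = 2.92e-04, and Rhag, 8.73 ± 0.37, adjusted p = 9.13e-06), while Car2, a carbonic anhydrase, did not pass (0.31 ± 1.08, adjusted p = 0.916). Of 9 heme synthesis genes, 8 rose and 1 did not pass, and 8 rose adjusted over the list alone (median 3.16, or 2.87 floored at 4, camera adjusted p = 0.00229, and adjusted p = 0.123 with an estimated correlation). Slc25a38 rose (5.22 ± 0.40, adjusted p = 8.96e-05), and Alas2, the red cell form of the first enzyme of the pathway, by at least 3.57-fold, adjusted p = 0.0327.

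Of 12 megakaryocyte genes, 1 rose, 10 fell and 1 did not pass, and 11 fell adjusted over the list alone (median -3.44, or -2.40 floored at 4, camera adjusted p = 0.00305, and adjusted p = 0.286 with an estimated correlation). Rab27b, which acts in granule release, fell by at least 38.5-fold, adjusted p = 4.36e-04, Itgb3, a platelet integrin chain, by at least 13.1-fold, adjusted p = 2.49e-05, and Fli1, a transcription factor of megakaryocytes (-5.38 ± 1.70, adjusted p = 0.0365). Of 17 immediate early and heat shock genes, 2 rose, 10 fell and 5 did not pass, with the same counts adjusted over the list alone (median -2.51, or -2.40 floored at 4, camera adjusted p = 0.0166, and adjusted p = 0.983 with an estimated correlation). Egr1 fell (-7.86 ± 0.35, adjusted p = 1.16e-05), and Nr4a1 by at least 38.9-fold, adjusted p = 0.00185. Genes of this list respond to tissue handling, and the list's adjusted p ranged from 2.35e-04 to 0.167 over its alternatives, the highest with only the blood arrays in the fit. The pan-hematopoietic list had 7 members that fell and 17 that did not pass, 3 falling adjusted over the list alone (median -2.54, camera adjusted p = 0.106). Lcp1 and Coro1a, actin-binding proteins of white blood cells, fell (-5.61 ± 1.60, adjusted p = 0.0247, and -5.78 ± 1.67, adjusted p = 0.0262). Among 13 myeloid genes, 5 rose and 3 fell (median 0.63, camera adjusted p = 0.533). The neutrophil granule genes Ngp and Camp rose (Ngp by at least 104-fold, adjusted p = 1.09e-04, and Camp by at least 20.03-fold, adjusted p = 4.23e-06), and Prtn3, a granule protease of earlier myeloid cells, fell (-6.56 ± 0.19, adjusted p = 3.41e-06). Of 8 lymphoid genes 3 fell, including Cd79b, a chain of the B cell receptor complex (-5.52 ± 0.34, adjusted p = 3.90e-05), and of 5 endothelial genes 3 fell, including Tie1 by at least 8.19-fold, adjusted p = 5.79e-05 (camera adjusted p = 0.351 and 0.195 for the lists).

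Of 17 genes of the DNA methylation machinery, 7 rose, 3 fell and 7 did not pass, with the same counts adjusted over the list alone (median 0.44, camera adjusted p = 0.351). Uhrf1, which guides maintenance methylation to newly copied DNA, rose (4.88 ± 0.31, adjusted p = 4.46e-05), and Gadd45a (5.79 ± 0.46, adjusted p = 1.03e-04). Dnmt3b, a de novo methyltransferase, fell (-4.37 ± 0.47, adjusted p = 3.67e-04), and Tet2, a dioxygenase that oxidises methylcytosine (-3.17 ± 0.58, adjusted p = 0.00404). Dnmt1, the maintenance methyltransferase, was at 12.62 ± 0.05 in MEP and 12.12 ± 0.00 in HSC and did not pass (0.50 ± 0.25, adjusted p = 0.143). Of 16 polycomb genes, 2 rose and 4 fell (median -0.61, camera adjusted p = 0.564). Suz12 and Ezh2, members of the complex that methylates histone H3 at lysine 27, rose (2.50 ± 0.23, adjusted p = 1.75e-04, and 2.44 ± 0.22, adjusted p = 1.84e-04), and Ezh1 fell (-2.02 ± 0.22, adjusted p = 4.23e-04). The largest rises were in Rhd, Slc38a5, Cldn13, Rhag, Sphk1, Trim10, Cdr2, Kel, Tspo2 and Nxpe2, and the largest falls in Adgrl4, Mecom, Hlf, Itih5, Mamdc2, Mmrn1, Hacd4, Fscn1, Procr and Zfp467, with Adgrl4, an endothelial adhesion receptor, at least 761-fold lower. In the same arrays the 3′ minus 5′ signal of the Actb control was 4.44 and 5.14 in HSC and 1.92 and 1.84 in MEP, a difference that goes with the HSC to MEP change in every list of this comparison. Leaving out any array changed the count to between 3825 and 6146.

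The comparison of EDif with EPro addresses the step from basal progenitors to differentiated epidermis. Genes of cell division and of the basal layer fell in EDif, and genes of the lipid barrier and of the outer epidermal layers were among those that rose. Sprr1a, a precursor protein of the cornified envelope, rose (4.88 ± 0.54, adjusted p = 0.00382), and Klk10, a kallikrein protease (6.07 ± 0.96, adjusted p = 0.0137). Cenpe, a motor protein of mitosis, fell by at least 20.5-fold, adjusted p = 0.00658, and Itgb4, the integrin chain that anchors basal cells to the basement membrane (-3.28 ± 0.45, adjusted p = 0.00876). Of 11730 genes 938 passed, 397 higher and 541 lower in EDif. Median centring moved the median of all genes from -0.02 to -0.19. This count moved with many single arrays: it was 260 without EPro replicate 1, 289 without EPro replicate 2, 448 without either MEP array, 559 without either HSC array, 1431 without either CLDC array or without both, and 2002 without EDif replicate 2, where the split turned to 1111 higher and 891 lower. It was 64 with only the skin arrays in the fit. The main fit shares its spread with the blood arrays. Among brighter genes their SD between replicates was 0.22 in MEP and 0.36 in HSC, against 0.42 in EPro and 1.10 in EDif. In a simulation on 11730 genes that kept the spread of each cell type, 28.5% of the genes called in this comparison were false when 200 changed by log2 4.

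Of 31 cell cycle genes, 24 fell and 7 did not pass, and 30 fell adjusted over the list alone (median -2.93, camera adjusted p = 8.48e-22, and adjusted p = 0.189 with an estimated correlation). Cdk1, the kinase that starts mitosis, fell (-4.05 ± 0.62, adjusted p = 0.0122), and Aurka by at least 8.32-fold, adjusted p = 0.00470. Pcna, the sliding clamp of DNA replication, did not pass (-0.39 ± 0.32, adjusted p = 0.543). The list's median was 0.99 higher on EDif replicate 1 than on replicate 2. Of 18 basal epidermis genes, 10 fell and 8 did not pass, and 14 fell adjusted over the list alone (median -1.92, camera adjusted p = 1.27e-09, and adjusted p = 0.189 with an estimated correlation). Dll1, a Notch ligand of basal cells, fell (-3.89 ± 0.38, adjusted p = 0.00247), Itga3 (-3.80 ± 0.42, adjusted p = 0.00395), and Cdh3, the P-cadherin gene (-3.74 ± 0.38, adjusted p = 0.00311). Trp63, the transcription factor of the basal layer, did not pass (-1.01 ± 0.32, adjusted p = 0.121).

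Of 22 epidermal lipid barrier genes, 7 rose and 15 did not pass, and 14 rose adjusted over the list alone (median 1.54, camera adjusted p = 4.76e-08, and adjusted p = 0.189 with an estimated correlation). Cyp4f39 and Ugcg, enzymes of acylceramide and glucosylceramide synthesis, rose (2.84 ± 0.65, adjusted p = 0.0440, and 2.78 ± 0.57, adjusted p = 0.0306), and Abca12, the lipid transporter of lamellar granules (2.72 ± 0.64, adjusted p = 0.0494). Of 15 spinous layer genes, 3 rose, also adjusted over the list alone, and 12 did not pass (median 1.11, camera adjusted p = 3.89e-04, and adjusted p = 0.521 with an estimated correlation). Endou rose (4.85 ± 0.58, adjusted p = 0.00488), and Dsc1, a desmosomal cadherin (2.02 ± 0.43, adjusted p = 0.0355). Of 26 cornified envelope and granular layer genes, 4 rose, 1 fell and 21 did not pass, with 8 risen and 1 fallen adjusted over the list alone (median 2.74, or 2.58 floored at 4, camera adjusted p = 3.93e-05, and adjusted p = 0.521 with an estimated correlation). Ivl, which encodes involucrin, rose (3.03 ± 0.62, adjusted p = 0.0305), Tgm3, a transglutaminase, fell by at least 5.51-fold, adjusted p = 0.0207, and Rptn, at 10.54 and 11.09 on the EDif arrays, did not pass (adjusted p = 0.0762). The median of this list was 1.05 without EPro replicate 1, 4.60 without EPro replicate 2, 4.18 without EDif replicate 1 and 1.76 without EDif replicate 2.

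Genes of the follicle were measured beside these. Of 16 follicle stem and outer root sheath genes, 5 rose, 1 fell and 10 did not pass, with 8 risen and 2 fallen adjusted over the list alone (median 1.24, camera adjusted p = 8.08e-04, and adjusted p = 0.189 with an estimated correlation). The list's median was 1.86 without EPro replicate 1. Foxc1 and Tbx1, transcription factors of follicle stem cells, rose (Foxc1, 6.64 ± 0.59, adjusted p = 0.00193, and Tbx1 by at least 15.3-fold, adjusted p = 0.0301), and Lgr6 fell (-2.40 ± 0.55, adjusted p = 0.0457). Of 8 companion layer and outer root sheath keratins, 2 rose and 1 fell, with 3 each way adjusted over the list alone (median 0.94, camera adjusted p = 0.607). Krt79, a keratin of the upper follicle and its duct, rose (5.15 ± 1.01, adjusted p = 0.0267). Of 5 sebocyte genes, 1 rose and 4 did not pass, and 4 rose adjusted over the list alone (median 2.215, camera adjusted p = 0.00190, and adjusted p = 0.311 with an estimated correlation). Plin2, a protein that coats lipid droplets, rose (2.215 ± 0.39, adjusted p = 0.0189), and the list's median was 1.01 without EDif replicate 1.

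Genes of other skin cells also differed between EDif and EPro, and the skin immune, pan-hematopoietic, melanocyte and fibroblast lists lay higher on EDif replicate 1, by medians of 6.10, 5.90, 6.31 and 4.02. Of 10 skin immune genes, 3 rose and 7 did not pass, and 8 rose adjusted over the list alone (median 6.40, or 5.93 floored at 4, camera adjusted p = 4.04e-06, and adjusted p = 0.451 with an estimated correlation). H2-Aa, a class II antigen-presenting gene, rose (5.88 ± 1.19, adjusted p = 0.0295), at 15.25 and 12.35 on the EDif arrays, and Cd74 (6.20 ± 1.22, adjusted p = 0.0274). The list's median was 3.46 without EDif replicate 1. Of 24 pan-hematopoietic genes, 3 rose, 1 fell and 20 did not pass, with 5 risen and 1 fallen adjusted over the list alone (median 3.04, or 2.45 floored at 4, camera adjusted p = 2.40e-04, and adjusted p = 0.615 with an estimated correlation). Laptm5 rose by at least 53.7-fold, adjusted p = 0.0441, and Myb, which is also a gene of dividing cells, fell by at least 13.9-fold, adjusted p = 4.47e-04. Of 9 melanocyte genes 1 rose, the transcription factor Mitf (3.33 ± 0.56, adjusted p = 0.0163), and Dct, an enzyme of pigment synthesis, did not pass (adjusted p = 0.108). The melanocyte list had a positive change (median 3.33, or 2.68 floored at 4, camera adjusted p = 0.00364, and adjusted p = 0.542 with an estimated correlation). Of 9 fibroblast genes, 2 rose, and 3 adjusted over the list alone (median 2.87, or 1.88 floored at 4, camera adjusted p = 0.00364, and adjusted p = 0.542 with an estimated correlation). Col3a1, a collagen of connective tissue, rose by at least 193-fold, adjusted p = 0.00506, and Vim, an intermediate filament of mesenchymal cells (5.53 ± 1.19, adjusted p = 0.0375). Without EDif replicate 1 these medians were 0.32 for the pan-hematopoietic list, 0.03 for melanocytes and 0.22 for fibroblasts. Without EDif replicate 2 they were 6.04, 6.34 and 5.52. Over alternatives the lists' adjusted p ranged from 1.85e-16 to 0.0546, 1.19e-08 to 0.147 and 8.76e-05 to 0.0729. Of 13 myeloid genes 2 rose, Csf1r by at least 109-fold, adjusted p = 0.0301, and Cebpa (1.53 ± 0.36, adjusted p = 0.0483) (median 0.34, or 0.00 floored at 4, camera adjusted p = 0.0266, and adjusted p = 0.311 with an estimated correlation). The myeloid median was 0.07 without EDif replicate 1, and its adjusted p ranged from 0.00360 to 0.0644 over its alternatives, the highest without either CLDC array.

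Of 17 genes of the DNA methylation machinery, 2 fell, Hells (-3.46 ± 0.36, adjusted p = 0.00338) and Uhrf1 (-3.46 ± 0.31, adjusted p = 0.00194), and 3 fell adjusted over the list alone (median -0.40, camera adjusted p = 0.0234, and adjusted p = 0.451 with an estimated correlation). Dnmt1 and Dnmt3b did not pass over all genes (adjusted p = 0.0560 and 0.124). The list's adjusted p ranged from 4.22e-04 to 0.369 over its alternatives, the highest without EDif replicate 2, and was 0.0544 without either CLDC array. Of the 15 sorting genes, 1 rose and 2 fell, with 5 and 3 adjusted over the list alone (median 2.35, or 1.55 floored at 4, camera adjusted p = 0.0370, and adjusted p = 0.370 with an estimated correlation). The adjusted p of that list ranged from 0.00219 to 0.543 over its alternatives, the highest with each probe set on its own. It was 0.0587 without either CLDC array, 0.130 without EPro replicate 2 and 0.0545 without EDif replicate 1. The largest rises were in Col3a1, Calhm5, Csf1r, Mfge8, Cytip, Adcy7, Gsdma, Ctss, Cryab and Lcp1. Of these, Calhm5 (at least 92.2-fold, adjusted p = 1.93e-04) and Cryab (7.16 ± 0.68, adjusted p = 0.00228) had EDif SDs of 0.05 and 0.09, while Csf1r, Cytip, Ctss and Lcp1 had SDs of 4.26, 4.66, 3.90 and 4.12. The largest falls were in Slc2a5, Tecrl, Ptprz1, Wnt16, Myb, Hoxc5, Depdc7, Trp73, Kif20a and Wdhd1. Slc2a5, a fructose transporter, fell by at least 27.8-fold, adjusted p = 2.40e-04, and Wnt16, a Wnt ligand, by at least 14.6-fold, adjusted p = 7.54e-05. Cytip, Ctss and Lcp1 did not pass without any 1 of the HSC, MEP, CLDC or EPro arrays, and Csf1r without any 1 of the HSC, MEP or EPro arrays. Mfge8, Adcy7 and Depdc7 did not pass without either EPro array, and Gsdma without EPro replicate 1. Over the alternatives the adjusted p ranged from 4.05e-04 to 0.234 for Cytip, 1.03e-04 to 0.189 for Csf1r and 2.36e-04 to 0.110 for Mfge8. Of the 54 named genes that passed, 31 did not pass without at least 1 of the arrays.

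CLDC against EPro sets cells labelled as a differentiated follicle layer against epidermal progenitors. Keratins of the inner root sheath and of the hair shaft were higher on both CLDC arrays, and genes of basal epidermis were lower. Krt25 and Krt27, keratins of the inner root sheath, were at least 2094-fold (adjusted p = 2.34e-07) and at least 1189-fold higher (adjusted p = 4.44e-07), and Krt35, a keratin of the hair shaft, at least 1492-fold higher (adjusted p = 2.34e-07). Lamb3 and Col7a1, basement membrane genes of basal cells, fell (Lamb3, -7.96 ± 0.37, adjusted p = 2.15e-05, and Col7a1 by at least 76.6-fold, adjusted p = 9.60e-06). Genes of melanocytes, skeletal muscle and fibroblasts were higher on the same arrays. Of 11730 genes 3213 passed, 1417 higher and 1796 lower. After quantile normalization the split was 1770 higher and 1466 lower, and median centring moved the median of all genes from -0.04 to -0.19. The count was 1498 without EPro replicate 1 and 1511 without EPro replicate 2, and 1302 with only the skin arrays. With own spreads, 23.6% of simulated calls, not of the 3213, were false when 200 of 11730 genes changed by log2 4.

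Of 10 inner root sheath genes, 8 rose, 1 fell and 1 did not pass, also adjusted over the list alone (median 10.06, or 8.39 floored at 4, camera adjusted p = 4.15e-10, and adjusted p = 0.0257 with an estimated correlation). Gata3, a transcription factor of this layer and of other skin cells, fell (-2.02 ± 0.54, adjusted p = 0.0330). All 15 hair shaft genes rose (median 7.69, or 6.06 floored at 4, camera adjusted p = 5.01e-16, and adjusted p = 0.193 with an estimated correlation). Krt33a and Krt31 rose by at least 1032-fold, adjusted p = 1.41e-06, and by at least 662-fold, adjusted p = 6.76e-07, and S100a3, a calcium-binding protein of the hair cuticle, by at least 611-fold, adjusted p = 2.34e-07. Of 16 follicle stem and outer root sheath genes, 7 rose, 2 fell and 7 did not pass, with 10 risen and 2 fallen adjusted over the list alone (median 2.25, camera adjusted p = 0.0183, and adjusted p = 0.332 with an estimated correlation). Lhx2, a transcription factor of follicle stem cells, rose by 5.92 ± 0.58, Gli1, a target of hedgehog signalling, by at least 7.23-fold, adjusted p = 0.00417, and Lgr6 fell (-4.54 ± 0.55, adjusted p = 0.00160). Without CLDC replicate 2 the list's median was 1.83 (adjusted p from 0.00166 to 0.170 over its alternatives). Of 8 companion layer and outer root sheath keratins, 1 rose and 4 fell (median -1.28, or -0.72 floored at 4, camera adjusted p = 0.528). Krt75 rose, as given above, and Krt16 and Krt6b fell (-5.86 ± 0.73, adjusted p = 0.00174; Krt6b by at least 2.83-fold, adjusted p = 0.0258).

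All 9 melanocyte genes rose (median 11.60, or 10.12 floored at 4, camera adjusted p = 8.52e-08, and adjusted p = 0.332 with an estimated correlation). Tyrp1 and Mlana, genes of the pigment granule, rose by at least 1984-fold, adjusted p = 0.00826, and by at least 1633-fold, adjusted p = 0.00422. All 8 muscle genes rose (median 10.04, or 8.83 floored at 4, camera adjusted p = 6.32e-09, and adjusted p = 0.332 with an estimated correlation). Myl1 and Tnnc2, genes of the contractile apparatus of skeletal muscle, rose by at least 1287-fold, adjusted p = 9.28e-06, and by at least 770.4-fold, adjusted p = 2.15e-05. Of 9 fibroblast genes, 8 rose and 1 did not pass (median 8.63, or 8.18 floored at 4, camera adjusted p = 1.42e-04, and adjusted p = 0.533 with an estimated correlation). Col3a1 rose by at least 2022-fold, adjusted p = 4.28e-04, and Col1a2 by at least 1440.2-fold, adjusted p = 0.00262. Of 10 skin immune genes, 5 rose and 5 did not pass, and 6 rose adjusted over the list alone (median 4.56, camera adjusted p = 0.00608, and adjusted p = 0.727 with an estimated correlation). H2-Eb1 rose by at least 61.3-fold, adjusted p = 0.0288, and H2-Aa (5.11 ± 1.19, adjusted p = 0.0200). Of 24 pan-hematopoietic genes, 5 rose, and 4 adjusted over the list alone (median 1.10, or 0.18 floored at 4, camera adjusted p = 0.0183, and adjusted p = 0.864 with an estimated correlation). Ptprc, the pan-leukocyte surface phosphatase, rose by at least 50.3-fold, adjusted p = 0.0445. This list's median was 0.67 without CLDC replicate 2, and -0.01 with sex-linked expression as a block (adjusted p = 0.256, in a range from 1.11e-05 to 0.344). Red cell genes were among those that rose: Alas2 by at least 348-fold, adjusted p = 9.76e-04, and Hbb-b2 by at least 196-fold, adjusted p = 8.83e-04, in lists that did not pass as a whole (camera adjusted p = 0.732 for heme synthesis and 0.0851 for erythroid genes).

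Of 18 basal epidermis genes, 12 fell and 6 did not pass, and 14 fell adjusted over the list alone (median -2.87, camera adjusted p = 7.61e-08, and adjusted p = 0.193 with an estimated correlation). Itgb4 fell (-5.17 ± 0.45, adjusted p = 3.97e-04), and Dll1 (-5.05 ± 0.38, adjusted p = 1.96e-04). Of 17 immediate early and heat shock genes, 10 fell and 7 did not pass, with 1 risen and 11 fallen adjusted over the list alone (median -1.64, camera adjusted p = 0.00145, and adjusted p = 0.604 with an estimated correlation). Socs3, Klf6 and Atf3 fell (-3.13 ± 0.65, adjusted p = 0.0134, -2.83 ± 0.32, adjusted p = 0.00124, and -2.50 ± 0.42, adjusted p = 0.00616). Of 26 cornified envelope and granular layer genes, 4 rose and 2 fell (median -0.22, or 0.07 floored at 4, camera adjusted p = 0.533). Sprr1a was higher (4.22 ± 0.54, adjusted p = 0.00197), and Hrnr lower by at least 66.98-fold, adjusted p = 0.00164. In the spinous list Endou and Mt4 rose (5.24 ± 0.58, adjusted p = 0.00104; 3.81 ± 0.40, adjusted p = 8.62e-04) and Krt1 was among 3 that fell (-2.85 ± 0.25, adjusted p = 3.86e-04; for the list, camera adjusted p = 0.524). Of 31 cell cycle genes 5 fell, and 3 adjusted over the list alone (median -0.12, camera adjusted p = 0.609). Mcm6, a replication helicase subunit, fell (-1.90 ± 0.25, adjusted p = 0.00240). The largest rises were in Krt25, Col3a1, Tyrp1, Mlana, Krt35, Krtap8-1, Car3, Krt27, Tyr and Prr9, and the largest falls in H60c, Slc22a4, Slc6a4, Serpinb7, Slc6a2, Slc2a12, Ndufa4l2, Rasgrp1, Fosl1 and Lamb3. H60c, an NKG2D ligand of skin cells, was at least 416-fold lower (adjusted p = 2.51e-06). Without each EPro array Tyrp1 no longer passed, and over its alternatives its adjusted p ranged from 2.93e-06 to 0.0674.

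The CLDC arrays were also compared with EDif. Inner root sheath and hair shaft genes and genes of cell division were higher on the CLDC arrays, and 12 of 22 lipid barrier and 7 of 15 spinous layer genes were lower. Krt25 and Krt35 rose by at least 2094-fold, adjusted p = 2.34e-07, and by at least 1492-fold, adjusted p = 2.34e-07. Bub1b and Ube2c, regulators of mitosis, rose (Bub1b by at least 30.4-fold, adjusted p = 0.00103, and Ube2c, 4.53 ± 0.72, adjusted p = 0.00625). Hrnr, which encodes the cornified envelope protein hornerin, was at least 232-fold lower (adjusted p = 9.58e-04), and Sptlc3, a subunit of the first enzyme of sphingolipid synthesis, fell (-5.29 ± 0.27, adjusted p = 4.38e-05). Of 11730 genes 2857 passed, 1398 higher and 1459 lower. After quantile normalization the split was 1867 higher and 1214 lower, with the median of all genes at 0.13. The count was 831 with only the skin arrays and 882 with each cell type weighted by its own spread. With own spreads, 61.1% of simulated calls, not of the 2857, were false when 200 of 11730 genes changed by log2 4.

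Of 31 cell cycle genes, 27 rose and 4 did not pass, and 29 rose adjusted over the list alone (median 2.94, camera adjusted p = 1.01e-12, and adjusted p = 0.368 with an estimated correlation). Aurka rose by at least 17.1-fold, adjusted p = 7.37e-04, and Pcna did not pass (0.09 ± 0.32, adjusted p = 0.874). Of 10 inner root sheath genes, 8 rose and 2 did not pass, also adjusted over the list alone (median 10.10, or 8.36 floored at 4, camera adjusted p = 8.01e-11, and adjusted p = 0.0227 with an estimated correlation). Krt73 rose by at least 1001-fold, adjusted p = 2.34e-07, and Krt28 by at least 749-fold, adjusted p = 5.09e-07. Of 15 hair shaft genes, 14 rose and 1 did not pass, and 15 rose adjusted over the list alone (median 7.51, or 5.98 floored at 4, camera adjusted p = 6.18e-16, and adjusted p = 0.293 with an estimated correlation). Krt33a rose by at least 1032-fold, adjusted p = 1.32e-06, and Foxn1, a transcription factor of the hair matrix, did not pass (3.86 ± 1.30, adjusted p = 0.0730). Of 22 epidermal lipid barrier genes, 1 rose, 12 fell and 9 did not pass, with 1 risen and 15 fallen adjusted over the list alone (median -2.28, or -2.01 floored at 4, camera adjusted p = 4.64e-05, and adjusted p = 0.368 with an estimated correlation). Abca12 fell by at least 21.3-fold, adjusted p = 0.00176, and Fa2h, a fatty acid hydroxylase (-4.59 ± 1.04, adjusted p = 0.0208). Of 15 spinous layer genes, 1 rose and 7 fell, with 1 and 8 adjusted over the list alone (median -1.79, camera adjusted p = 0.00612, and adjusted p = 0.532 with an estimated correlation). Krt1 fell (-3.58 ± 0.25, adjusted p = 1.83e-04), and Krt10, at the top of the EDif arrays, by at least 2.45 log2 units (adjusted p = 0.0251). The spinous median was -1.34 without EDif replicate 2 and -1.17 without CLDC replicate 2 (adjusted p from 4.77e-04 to 0.145 over its alternatives).

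Of 26 cornified envelope and granular layer genes, 1 rose, 3 fell and 22 did not pass, with 1 risen and 2 fallen adjusted over the list alone (median -2.72, or -2.24 floored at 4, camera adjusted p = 0.0200, and adjusted p = 0.585 with an estimated correlation). Tgm3 rose by at least 21.7-fold, adjusted p = 0.00197, and Sprr2d fell by at least 2.15-fold, adjusted p = 0.00313. The median was -4.36 without CLDC replicate 1, -0.60 without CLDC replicate 2 and -1.85 without EDif replicate 2. The list's adjusted p ranged from 3.19e-04 to 0.310 over its alternatives. Of 18 basal epidermis genes, 2 rose, 9 fell and 7 did not pass, with 2 and 11 adjusted over the list alone (median -1.24, camera adjusted p = 0.00122, and adjusted p = 0.405 with an estimated correlation). Lamb3 fell (-5.22 ± 0.37, adjusted p = 2.18e-04), while Sparc, a matrix protein also made by fibroblasts, and Cdh3 rose (4.64 ± 1.20, adjusted p = 0.0319; 4.25 ± 0.38, adjusted p = 6.47e-04). Of 17 immediate early and heat shock genes, 9 fell, and 10 adjusted over the list alone (median -1.43, camera adjusted p = 2.61e-04, and adjusted p = 0.532 with an estimated correlation). Atf3 fell (-2.32 ± 0.42, adjusted p = 0.00987).

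All 8 muscle genes rose (median 10.04, or 8.47 floored at 4, camera adjusted p = 2.33e-09, and adjusted p = 0.368 with an estimated correlation). Myl1 rose by at least 1287-fold, adjusted p = 1.38e-05. Of 9 melanocyte genes, 6 rose and 3 did not pass, and 9 rose adjusted over the list alone (median 7.52, or 6.79 floored at 4, camera adjusted p = 9.12e-06, and adjusted p = 0.441 with an estimated correlation). Gpr143 and Slc45a2, membrane proteins of the pigment granule, rose by at least 187-fold, adjusted p = 7.10e-06, and by at least 243-fold, adjusted p = 7.86e-06. The melanocyte median was 3.62 without EDif replicate 2. Of 9 fibroblast genes, 3 rose, and 6 adjusted over the list alone (median 5.09, or 4.83 floored at 4, camera adjusted p = 0.00921, and adjusted p = 0.532 with an estimated correlation). Lum, a proteoglycan of connective tissue, rose by at least 222-fold, adjusted p = 0.00630, and Col1a1 (7.37 ± 1.84, adjusted p = 0.0287). The fibroblast median was 2.27 without CLDC replicate 2 and 2.60 without EDif replicate 2. The list's adjusted p ranged from 7.57e-05 to 0.274 over its alternatives. No skin immune gene passed (median -1.29, camera adjusted p = 0.401; H2-Aa, -0.77 ± 1.19, adjusted p = 0.679). In the sebocyte list Scd3 and Scd1, fatty acid desaturases, fell (Scd3 by at least 46.7-fold, adjusted p = 0.00427; Scd1, -1.35 ± 0.25, adjusted p = 0.0102; for the list, camera adjusted p = 0.0832). Of the genes of DNA methylation, Uhrf1, Hells and Dnmt1 rose (3.34 ± 0.31, adjusted p = 7.28e-04; 1.94 ± 0.36, adjusted p = 0.0107; 1.05 ± 0.25, adjusted p = 0.0236) and Uhrf2 fell (-1.19 ± 0.26, adjusted p = 0.0176; median 0.41, camera adjusted p = 0.106). The largest rises were in Krt25, Krt35, Krtap8-1, Krt27, Prr9, Krt33a, Krtap11-1, Krt73, Myl1 and Krt28, and the largest falls in Hrnr, Serpinb7, Aldh3a1, Aadacl2fm1, Slc22a4, H60c, Clca3a1, Slc6a14, Ccl22 and Rasgrp1. Ccl22, a chemokine of antigen-presenting cells, was at least 36.7-fold lower (adjusted p = 2.81e-06). Slc6a14 did not pass without CLDC replicate 2 (adjusted p = 0.0510), and its adjusted p ranged from 0.00356 to 0.178 over its alternatives.

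**Figure D3:**
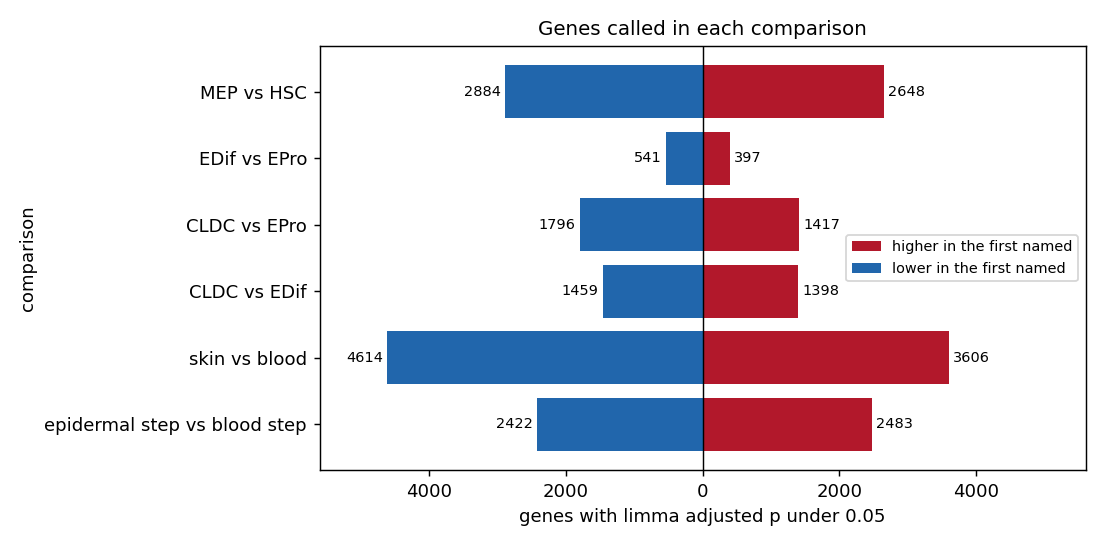
Number of the 11730 tested genes past the adjusted p threshold in each comparison, bars to the right for genes higher in the first named group and to the left for genes lower. Skin against blood has the most (3606 higher, 4614 lower) and EDif against EPro the fewest (397 higher, 541 lower).

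Comparing the 3 skin with the 2 blood cell types describes the lineages as a whole. Strain, tissue and cell release go with lineage and cannot be told apart from it, and sex goes with it in part. The 3′ minus 5′ signal goes with it too, from 2.87 to 4.94 (Gapdh) and 1.84 to 5.14 (Actb) on the blood arrays and from 0.32 to 0.61 and 1.17 to 1.49 on the skin arrays. Spinous, basal and adhesion genes were higher in skin, and 17 of 19 erythroid and 16 of 24 pan-hematopoietic genes were higher in blood. Dsp, the desmosomal linker protein desmoplakin, was at least 2636-fold higher in skin (adjusted p = 6.46e-08), and Trp63 at least 641-fold (adjusted p = 1.40e-07). Tfr2, a transferrin receptor of red cell precursors, was at least 889-fold lower in skin (adjusted p = 2.36e-07), and Tal1, a master regulator of blood formation, at least 168-fold (adjusted p = 4.89e-08). Of 11730 genes 8220 passed, 3606 higher and 4614 lower in skin. The median of all genes was -0.22 as deposited, -0.24 after quantile normalization and -0.35 after median centring. With cell type as a random block in a fit of 2 groups, 1694 genes passed, 948 higher and 746 lower in skin, and 4540 in that fit without the block.

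All 15 spinous layer genes were higher in skin (median 10.38, or 8.80 floored at 4, camera adjusted p = 1.98e-09, and adjusted p = 0.201 with an estimated correlation), as were 17 of 18 basal epidermis genes (median 6.64, or 4.95 floored at 4, camera adjusted p = 6.33e-10, and adjusted p = 0.130 with an estimated correlation). Lgals7, a galectin of stratified epithelium, was higher by at least 1756-fold, adjusted p = 6.46e-08, and Krt15 by at least 1006-fold, adjusted p = 4.89e-08. Of 20 epithelial adhesion genes, 18 were higher and 2 lower (median 8.10, or 6.74 floored at 4, camera adjusted p = 8.69e-09, and adjusted p = 0.178 with an estimated correlation). Epcam was higher by at least 567-fold, adjusted p = 4.65e-07. The cornified list had 20 higher and 6 that did not pass, 23 higher adjusted over the list alone (median 5.54, or 4.46 floored at 4, camera adjusted p = 2.13e-06, and adjusted p = 0.272 with an estimated correlation). Ivl was higher by at least 147-fold, adjusted p = 2.95e-06. Of 22 lipid barrier genes, 16 were higher and 1 lower (median 3.61, or 2.37 floored at 4, camera adjusted p = 1.93e-05, and adjusted p = 0.201 with an estimated correlation). Elovl4, which elongates the fatty acids of skin ceramides, was higher by at least 309.7-fold, adjusted p = 1.70e-07. All 8 companion layer and outer root sheath keratins (median 8.49, or 6.79 floored at 4, camera adjusted p = 2.38e-05, and adjusted p = 0.201 with an estimated correlation), all 10 inner root sheath genes (median 3.85, or 3.28 floored at 4, camera adjusted p = 3.96e-06, and adjusted p = 0.104 with an estimated correlation) and all 15 hair shaft genes were higher in skin (median 3.30, or 2.53 floored at 4, camera adjusted p = 2.13e-06, and adjusted p = 0.201 with an estimated correlation). The hair shaft mean was 11.40 and 10.40 on the CLDC arrays, at most 3.20 on the EPro and EDif arrays and at most 2.32 on the blood arrays, and the inner root sheath mean was 12.79 and 12.37, at most 4.32 and at most 3.34. Krt17 was higher by at least 364-fold, adjusted p = 2.53e-06, Gata3 (7.46 ± 0.35, adjusted p = 3.64e-06), and Krt32 by at least 8.98-fold, adjusted p = 1.78e-05. Of 16 follicle genes 12 were higher and 3 lower (median 3.86, or 2.30 floored at 4, camera adjusted p = 0.00420, and adjusted p = 0.201 with an estimated correlation). Sox9 was higher by at least 12.6-fold, adjusted p = 1.46e-04.

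Of 17 immediate early and heat shock genes, 15 were higher in skin, 16 adjusted over the list alone (median 6.34, camera adjusted p = 5.06e-08, and adjusted p = 0.201 with an estimated correlation). Atf3 was higher by at least 1240.3-fold, adjusted p = 2.53e-07, and Hspa1a, an inducible heat shock protein, by at least 617-fold, adjusted p = 2.62e-07. Genes of other skin cells were also higher: all 9 melanocyte genes (median 4.98, or 4.13 floored at 4, camera adjusted p = 0.00197, and adjusted p = 0.349 with an estimated correlation), all 8 muscle genes (median 3.35, or 2.75 floored at 4, camera adjusted p = 0.00197, and adjusted p = 0.349 with an estimated correlation), 7 of 9 fibroblast genes (median 4.23, or 3.35 floored at 4, camera adjusted p = 0.0198, and adjusted p = 0.437 with an estimated correlation) and 4 of 5 sebocyte genes (median 3.81, or 2.17 floored at 4, camera adjusted p = 0.0205, and adjusted p = 0.247 with an estimated correlation). The muscle mean was 13.75 and 11.43 on the CLDC arrays, at most 3.27 on the EPro and EDif arrays and at most 3.11 on the blood arrays. The melanocyte mean was 13.41 and 12.93 on the CLDC arrays, 8.65 and 4.04 on the EDif arrays, and at most 3.44 on the EPro and 3.34 on the blood arrays. Dct was higher by at least 60.3-fold, adjusted p = 0.00151, Acta1 by at least 7.75-fold, adjusted p = 7.08e-04, Postn by at least 746-fold, adjusted p = 1.44e-05, and Scd1 (6.92 ± 0.16, adjusted p = 2.39e-07). Among skin immune genes 2 were higher and 1 lower (median 1.49, or 1.60 floored at 4, camera adjusted p = 0.258). Cd207 was higher by at least 17.2-fold, adjusted p = 0.00676, and Ptprc lower (-4.80 ± 1.32, adjusted p = 0.0141).

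Of 19 erythroid genes, 17 were lower in skin and 1 higher (median -4.84, or -4.49 floored at 4, camera adjusted p = 2.13e-06, and adjusted p = 0.130 with an estimated correlation). Car1, a carbonic anhydrase of red cells, was lower by at least 422-fold, adjusted p = 3.34e-06, and Nfe2 by at least 193-fold, adjusted p = 6.46e-08. Of 24 pan-hematopoietic genes, 16 were lower and 8 did not pass (median -4.84, or -4.14 floored at 4, camera adjusted p = 3.08e-04, and adjusted p = 0.420 with an estimated correlation), among them Ikzf1, a transcription factor of lymphoid and stem cells (-8.24 ± 1.38, adjusted p = 0.00149), which did not pass with cell type as a random block (adjusted p = 0.133, in a range from 1.07e-06 to 0.133 over its alternatives). The list mean was 8.81 on EDif replicate 1, above both MEP arrays (8.66 and 8.23). Of 19 blood stem cell genes, 11 were lower and 1 higher (median -2.58, or -2.28 floored at 4, camera adjusted p = 0.00347, and adjusted p = 0.178 with an estimated correlation), among them Hoxa9 (-6.29 ± 0.47, adjusted p = 3.09e-05). The megakaryocyte list had 9 lower and 1 higher (median -2.18, or -1.46 floored at 4, camera adjusted p = 0.00714, and adjusted p = 0.201 with an estimated correlation). Pf4, a platelet chemokine, was lower (-5.37 ± 0.54, adjusted p = 1.23e-04). Both differences lie in HSC: the stem cell mean was at least 10.68 there, at most 4.55 in MEP and at least 4.91 in skin, and the megakaryocyte mean at least 7.64, at most 4.71 and at most 4.75. The myeloid list had 10 lower and 2 higher (median -2.82, or -1.93 floored at 4, camera adjusted p = 0.0177, and adjusted p = 0.201 with an estimated correlation). Prtn3 was lower by at least 26.3-fold, adjusted p = 1.40e-07, and Cebpa, a transcription factor of myeloid cells that skin also uses, higher by at least 102-fold, adjusted p = 4.87e-07. The adjusted p of the myeloid list reached 0.0589 with each probe set on its own, from 0.00150. Of 31 cell cycle genes, 21 were lower in skin and 1 higher (median -1.48, camera adjusted p = 6.37e-04, and adjusted p = 0.409 with an estimated correlation). This lies in MEP, with means of 12.04 and 12.06, while HSC (8.26 and 7.93) lay under EPro and CLDC (at least 9.36). Cdc6, a replication licensing factor, was lower (-5.34 ± 0.18, adjusted p = 1.01e-06). Of 17 DNA methylation genes, 5 were higher and 8 lower, 6 and 8 adjusted over the list alone (median 0.15, camera adjusted p = 0.840). Tet1 was lower by at least 17.6-fold, adjusted p = 9.30e-05, and Dnmt3b (-4.33 ± 0.30, adjusted p = 2.19e-05). Of 16 polycomb genes, 9 were lower and 1 higher (median -0.57, camera adjusted p = 0.122). Cbx6 was lower (-3.92 ± 0.31, adjusted p = 3.90e-05). In the heme list 5 of 9 were lower (camera adjusted p = 0.0656). Of the sorting genes 7 were higher and 3 lower (median 1.94, or 1.32 floored at 4, camera adjusted p = 0.0220, and adjusted p = 0.201 with an estimated correlation), a list whose adjusted p reached 0.0646 without EDif replicate 1, from 0.00152. The 10 genes highest in skin were Dsp, Lgals7, Dmkn, Krt15, Krtdap, Krt14, Pof1b, Fxyd3, Atf3 and Anxa8, and the 10 lowest Tfr2, Kcnn4, Car1, Hemgn, Tal1, Nfe2, Spn, Car2, Iqgap2 and Ikzf1.

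Whether genes moved alike when blood and epidermal cells differentiated was tested as the difference of the changes, EDif minus EPro less MEP minus HSC. Genes of cell division differed: all 31 cell cycle genes rose in MEP, while 24 fell in EDif, and all 31 were called in the difference (median -6.40, camera adjusted p = 1.04e-16, and adjusted p = 0.277 with an estimated correlation). Aurka rose at least 145-fold in the blood step and fell at least 8.32-fold in the epidermal step (adjusted p = 6.15e-05 for the difference), and Kif20a, a mitotic motor protein, fell by at least 15.2-fold in the epidermal step and also differed (adjusted p = 4.29e-05). Of 19 blood stem cell genes, 18 fell in MEP and 1 in EDif, and 16 were called higher in the difference, 17 adjusted over the list alone (median 6.34, or 5.71 floored at 4, camera adjusted p = 1.04e-06, and adjusted p = 0.0957 with an estimated correlation). Mecom was among them (adjusted p = 1.69e-04). In all, 4905 of 11730 genes passed, 2483 with the higher change in the epidermal step and 2422 with the lower. After median centring the split was 1990 and 2915, and the median of all genes moved from 0.10 to -0.30. Of 515 genes called in both steps, 382 went in opposite directions, 241 of them up in MEP and down in EDif, and 133 went the same way.

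Of 19 erythroid genes, 14 were lower in the difference and 1 higher (median -5.07, or -5.19 floored at 4, camera adjusted p = 2.68e-05, and adjusted p = 0.184 with an estimated correlation). Rhag was among the lower ones (adjusted p = 6.81e-05). Of 9 heme genes 5 were lower, with 1 higher and 7 lower adjusted over the list alone (median -3.58, or -3.02 floored at 4, camera adjusted p = 0.00630, and adjusted p = 0.184 with an estimated correlation). Alad differed by -4.28 ± 0.33, adjusted p = 1.69e-04. The megakaryocyte list had 8 higher and 1 lower, 10 and 1 adjusted over the list alone (median 3.98, or 2.67 floored at 4, camera adjusted p = 0.00630, and adjusted p = 0.291 with an estimated correlation). Vwf was among the higher ones (adjusted p = 0.0179). Of 18 basal epidermis genes, 11 were lower and 1 higher, 11 and 2 adjusted over the list alone (median -1.95, or -1.84 floored at 4, camera adjusted p = 0.00684, and adjusted p = 0.518 with an estimated correlation). Itgb1 differed by -5.16 ± 0.79, adjusted p = 0.00252. Of 22 lipid barrier genes, 8 were higher and 1 lower, 9 and 1 adjusted over the list alone (median 1.62, or 1.75 floored at 4, camera adjusted p = 0.0293, and adjusted p = 0.614 with an estimated correlation). Cers4, a ceramide synthase, differed by 7.08 ± 0.73, adjusted p = 4.95e-04. The adjusted p of the lipid list ranged from 0.00860 to 0.152 over its alternatives, the highest without EDif replicate 2, where the median was 1.49. The immediate early list had 10 higher and 1 lower (median 2.35, or 2.01 floored at 4, camera adjusted p = 0.0146, and adjusted p = 0.719 with an estimated correlation). Egr1 differed by 7.61 ± 0.49, adjusted p = 9.11e-05, beside the 3′ signal difference of HSC and MEP given above. Of 10 skin immune genes 7 were higher, 9 adjusted over the list alone (median 8.56, or 7.89 floored at 4, camera adjusted p = 0.00661, and adjusted p = 0.719 with an estimated correlation). H2-Aa differed by 11.83 ± 1.68, adjusted p = 0.00187. Of 24 pan-hematopoietic genes 10 were higher and 1 lower, 11 and 1 adjusted over the list alone (median 4.84, or 4.45 floored at 4, camera adjusted p = 0.00630, and adjusted p = 0.771 with an estimated correlation). Lcp1 differed by 12.77 ± 2.26, adjusted p = 0.00458. Both lists lay higher on EDif replicate 1, and without that array their medians were 5.38 and 2.82. Without EDif replicate 2 the pan-hematopoietic median was 7.67.

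Of the genes of DNA methylation, 7 were lower and 3 higher in the difference (median -0.71, camera adjusted p = 0.0762). Uhrf1 differed by -8.35 ± 0.44, adjusted p = 4.94e-05, and Hells by -6.70 ± 0.51, adjusted p = 1.61e-04. Of the polycomb genes 6 were higher and 2 lower (median 0.72, camera adjusted p = 0.467). Ezh2 differed by -3.55 ± 0.31, adjusted p = 2.71e-04, and Cbx7 was among the higher ones (adjusted p = 0.0110). The largest positive differences were in Rgs1, Nfatc2, Ctla2b, Fstl1, Grasp, Mfge8, Spata13, Hacd4, Ldhb and P2ry10, and the largest negative ones in Kif20a, Aurka, Plk1, Hmmr, Cenpf, Aurkb, Nek2, Esco2, Orc1 and Rhd. Nfatc2, a calcium-responsive transcription factor, differed (adjusted p = 2.16e-05), and Ldhb, a lactate dehydrogenase subunit (adjusted p = 4.83e-05). Grasp and P2ry10 did not pass without some single arrays, with adjusted p up to 0.147 and 0.0679 over their alternatives, from 4.30e-05 and 0.00123. 

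**Figure D4:**
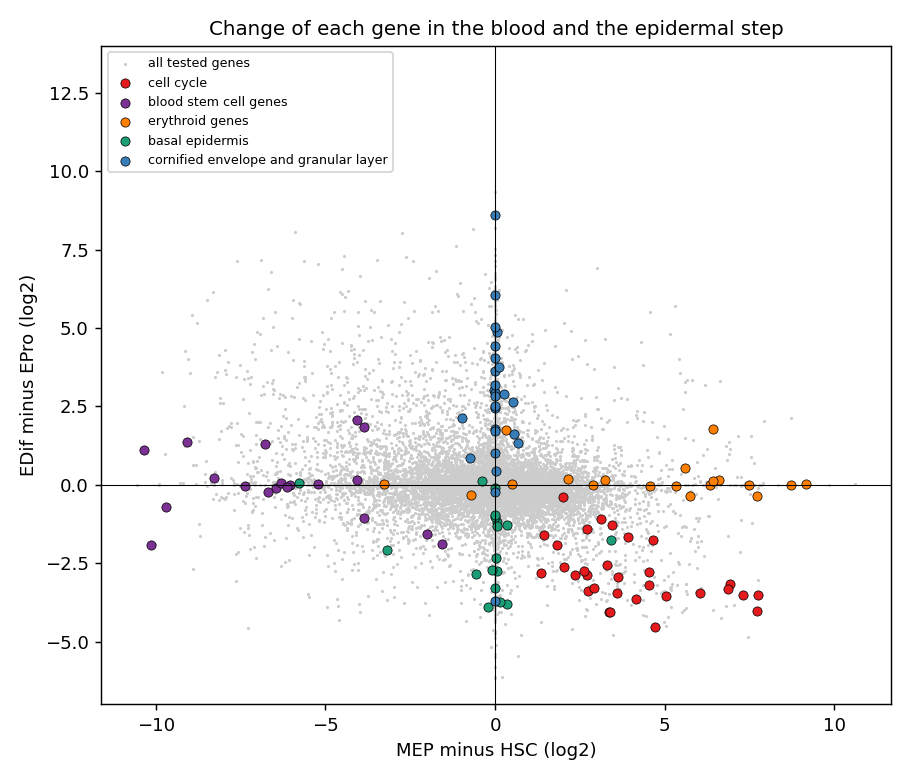
Change of each of the 11730 tested genes from HSC to MEP (horizontal axis, log2) and from EPro to EDif (vertical axis, log2), with 5 gene lists coloured and the other genes grey. The cell cycle genes lie to the right of 0 and below 0, and the blood stem cell genes lie to the left of 0.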

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

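The tests of explanations in this part were chosen after the result was seen, except the test of probe sets for the genes higher in MEP, which was set out before its value was seen.

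Hair, melanocyte and muscle genes on the arrays labelled CLDC. On the lower of the 2 arrays the mean of the 8 muscle genes lay 8.16 log2 units above the highest EPro or EDif array, as cells of other types, or their RNA, in the sorted samples would give, and Myl1 (14.98 and 13.68), Tyrp1 (15.25 and 14.66) and Dct (15.56 and 15.37) were abundant on both. No gene of the muscle and melanocyte lists is in another list. Gates on the red K6 reporter, β1 integrin, CD34 and the Lhx2 reporter were meant to remove such cells. Yet Lhx2 (12.92 and 13.09) and Cd34 (7.66 and 12.30) were detected, and other cells stay a hypothesis. An exchange with an EPro or EDif array is argued against by the inner root sheath list, whose lower CLDC mean lay 8.05 above the highest of those arrays, and a cause in a single CLDC array by the hair shaft list, whose median change from EPro was at least 7.18 without either array (7.18 and 8.60). A difference between the companion layer and other follicle layers was not tested, since no other layer was sorted.

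The EDif arrays lie apart at 3224 genes. The median of the skin immune list was 6.10 log2 units higher on replicate 1. H2-Aa was at 15.25 and 12.35, Cd74 at 15.42 and 11.34 and Cd207 at 14.75 and 8.66. Other skin cells, or their RNA, in that sample would give this. They are a hypothesis, and the gate on the K10 reporter was meant to remove them. The immune list shares Ptprc and Cd3g with other lists, and epidermis holds Langerhans cells and T cells. The sex of the animals as the whole difference is argued against by the EPro arrays, which split alike on sex-linked genes and were 2-fold apart at 796 genes. More basal cells in the other sample cannot be told apart from the values, since the basal list differed by 0.58, between the bounds set, and no biological explanation was tested.

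Signal toward the 3′ end, seen in control probe sets that no comparison uses, differed between the blood types: 3′ minus 5′ was 4.44 and 5.14 for Actb and 4.30 and 4.94 for Gapdh in HSC, and 1.92 and 1.84, and 2.87 and 2.96, in MEP, all above the skin arrays (at most 1.49 and 0.61), so it goes with every difference of skin from blood as well. Loss of signal away from the 3′ end lowers HSC, so it could give falls in MEP only if scaling lifted the rest of HSC; the controls added after labelling, which it spares, lay 0.33 log2 units higher in HSC (at most 0.54 for any of 9), which argues against it for the genes lower in MEP (median fall 2.65). For genes higher in MEP it stays open. Dimmer minus brightest probe set had a median of -0.23 over 1258 higher genes and 0.77 over 1127 lower genes. The sum, 0.54, was over the 0.2 set before, as loss would give. It rests on the lower genes, whose falls near the lowest value may be compressed in dim probe sets. Of the dimmer probe sets, 84.7% and 85.4% changed in the direction of the brightest. No biological explanation was tested.

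Poly-A controls, used in no comparison, had means of 4.87 and 5.19 in HSC, 7.34 and 7.02 in MEP and 13.6 on CLDC replicate 1. CLDC replicate 2, at 2.34, was near the lowest value and far from the other 5 skin arrays (at least 11.33, gap over range 0.799). Of 14 groups tested for a far sample this was the only such sample, and chance gives about 1 in 20.

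The steps in blood and epidermis differed, by the test of the difference, at 4905 genes, and 382 genes called in both steps went in opposite directions. Lists with a difference between the steps had medians of 6.34 (blood stem cell, epidermal step 0.01), -5.07 (erythroid, 0.01), -3.58 (heme, 0.02) and 3.98 (megakaryocyte, 0.03). For these the difference lies in the blood step. The others had -6.40 (cell cycle), -1.95 (basal), 1.62 (lipid barrier), 4.84 (pan-hematopoietic), 2.35 (immediate early) and 8.56 log2 units (skin immune). With an estimated correlation none of the 10 passed (adjusted p from 0.0957 to 0.771), and without EDif replicate 1 the medians were 2.82 (pan-hematopoietic) and 5.38 (skin immune).

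For skin against blood, in the fit with 2 groups, 1 of 100 splits of the 10 arrays into 6 and 4, the real one, called as many genes (4540), and the highest of the others called 1296, with EPro and EDif against the rest. Arrays of a cell type are alike, so splits that keep cell types whole are the closer comparison. Of these, 1 of 10, the real one, called as many, the highest other was the same, and 10 splits are too few for a share under 0.05.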

How the results depend on the processing

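The fits with weights, without the CLDC arrays, with a block for sex-linked expression and with a crossed block were chosen after the result was seen. Of 1748 values of the 72 called lists, 1643 kept direction and call, 104 lost the call and 1 reversed, and 70 of the losses came with the estimated correlation. For named genes 6693 values of 294 results gave 6210 that kept both, 455 weaker and 28 stronger, with 0 reversed. Of the named genes called, 44 of 50 in MEP against HSC, 8 of 54 in EDif against EPro, 44 of 55 in CLDC against EPro, 28 of 45 in CLDC against EDif, 37 of 43 in skin against blood and 30 of 33 in the difference of the steps were called under every alternative. The reversed value was the pan-hematopoietic list for CLDC against EPro, with a median of -0.0149 under the block for sex-linked expression (adjusted p = 0.256, in a range from 1.11e-05 to 0.344); the cause was not tested.

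With each probe set on its own the counts were 11641 (MEP against HSC), 1558 (EDif against EPro), 6437 (CLDC against EPro), 5351 (CLDC against EDif), 16729 (skin against blood) and 10055 (difference of the steps), since more features are tested. With only the skin arrays, EDif against EPro had 64, CLDC against EPro 1302 and CLDC against EDif 831; the cause was not tested. Skin against blood as 2 groups had 4540, and 1694 (948 higher, 746 lower) with cell type as a random block (consensus correlation 0.782), as the spread between cell types enters the error. With weights CLDC against EDif had 882, and without the CLDC arrays EDif against EPro had 1431; the cause was not tested. The side with more called genes turned under 4 of 25 alternatives in MEP against HSC, 1 of 25 in EDif against EPro, 2 of 24 in CLDC against EPro, 11 of 25 in CLDC against EDif, 1 of 25 in skin against blood and 9 of 25 in the difference of the steps. All other alternatives that keep the 10 arrays left the counts within 1.5 times.

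With 1 array left out, the counts ranged from 3825 to 6146 for MEP against HSC, 260 to 2002 for EDif against EPro, 1498 to 4029 for CLDC against EPro, 1947 to 3765 for CLDC against EDif, 7107 to 8640 for skin against blood and 3386 to 5695 for the difference of the steps. The array left alone in its cell type is assumed to vary like the other groups, and the cause was not tested.

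With the replicate block the counts were 5298, 730, 2839, 2435, 8064 and 4568 in the order above, and it ended the call of 0 of the 72 lists. Deviations from the group means correlated at 0.20 between EDif and EPro, -0.22 between CLDC and EDif, -0.12 between CLDC and EPro and -0.06 between MEP and HSC. The labels give no pairing, while EPro and EDif arrays of the same number split alike on the sex-linked genes, so pairing stays open. With the CLDC numbers crossed, CLDC against EDif had 2730 genes in place of 2857, and 11 of 11 lists kept their call.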

Other observations

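Single genes of epithelial adhesion differed, in a list that did not pass. In MEP against HSC, Krt18, a keratin of simple epithelia, fell by at least 168-fold, adjusted p = 1.04e-04, and Perp, a desmosomal membrane protein, by at least 15.8-fold, adjusted p = 2.91e-05, among 4 of 20 genes that fell and 1 that rose (median -0.00, camera adjusted p = 0.533). In EDif against EPro, Cldn4, a tight junction protein, rose (5.68 ± 0.85, adjusted p = 0.0113), and Dsg2 and Grhl2, a cadherin of desmosomes and a transcription factor of epithelia, fell (-2.72 ± 0.38, adjusted p = 0.00905, and -1.76 ± 0.38, adjusted p = 0.0371), with 1 gene risen and 3 fallen of 20 (median 0.08, camera adjusted p = 0.542).

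On the arrays labelled CLDC, 4 of 13 myeloid genes were higher than in EPro, among them Lyz2, a lysozyme of macrophages, by at least 174-fold, adjusted p = 0.00837, and Csf1r by at least 119-fold, adjusted p = 0.0118 (median 0.14, or 0.00 floored at 4, camera adjusted p = 0.0616). Of 16 polycomb genes 2 rose and 1 fell (median 0.02, camera adjusted p = 0.600), with Phc1 higher by at least 16.8-fold, adjusted p = 0.00319. Mycn, a transcription factor on the blood stem cell list, rose by at least 50.2-fold, adjusted p = 4.18e-04, and Mllt3 of the same list fell (-3.35 ± 0.28, adjusted p = 3.52e-04), with 3 genes risen and 3 fallen of 19 (median 0.70, or 0.31 floored at 4, camera adjusted p = 0.308).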
